A study of Rattus norvegicus with 12 samples.

How the data were processed

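Gene expression was measured by bulk RNA sequencing in 12 libraries of rat cells labelled PC12, 4 each of the groups OGDR, MSC and rTMS_MSC. The series text speaks of 20 samples and of a microarray, while the labels describe 12 sequencing libraries, and these 12 were analysed. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was captured with oligo(dT) and complementary DNA was primed with random primers. The strand setting of the read counting is not given in the sources used here. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to the rat genome build mRatBN7.2 and counted per gene with HTSeq 0.11.2, and DESeq2 1.40.1 was used for their own testing. The deposited table gives a raw count for each of 30454 Ensembl genes in each library, of which 26135 carried a gene symbol. It also holds 5 HTSeq summary lines, which were left out of library sizes and tests. Reads that fell on no feature made up 51.7285% to 52.7141% of all reads in the table.

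The counts were analysed with R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 on the 3 groups (minimum count 10, minimum total 15), which left 13692 of 20776 genes with at least 1 count. Libraries were scaled by TMM, and 1 quasi-likelihood model (glmQLFit and glmQLFTest) with a mean per group was fitted to all 12 libraries. The 3 comparisons were contrasts of group means, with 2-sided p-values adjusted by Benjamini-Hochberg over all tested genes and a threshold of 0.05. Replicate numbers were not used as a block in this fit. CPM, in which each count is scaled to the same library total, used the TMM-scaled library sizes, and log2 values for principal components used a prior count of 2. For a gene with no count in 1 group, the fold is a floor that takes 3 counts over that whole group as the most that could have been missed. For a gene with 1 count in a group, the ratio of summed counts is given with an exact interval. Depth was 18246250 to 20471838 counts in genes per library, at which a gene at 1 CPM has about 20 counts per library.

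Gene lists were chosen before the data were examined, 34 in number. They covered inflammatory cytokines and chemokines, NF-kB, inflammasome, interferon and antigen presentation, hypoxia, glycolysis, nuclear-encoded oxidative phosphorylation, the mitochondrial genome, the integrated stress response, chaperones of the endoplasmic reticulum, heat shock, the antioxidant response, p53, apoptosis, ferroptosis, autophagy and lysosome. They further covered DNA replication, mitosis, immediate early genes, ERK feedback, neurotrophic factors, neurite outgrowth, chromaffin identity, synaptic vesicles, ion channels, cholesterol, fatty acids, cytosolic ribosomal proteins, TGF-beta and YAP targets, extracellular matrix, and markers of stromal, macrophage, endothelial and glial cells. Of 928 symbols, 895 matched the table. Each list with at least 5 tested members was tested with camera on voom values (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the 34 lists. Changed members were also counted after an adjustment over the list alone.

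Genes were named by a rule of 3 parts. It took the 8 largest changes per direction among genes with adjusted p under 0.05, at least 5 CPM in the higher group, a symbol, and no overlap between the 4 values of each group. It took up to 4 members with the smallest p of each list described. It took a panel that included Il1b, Il6, Tnf, Nlrp3, Nfkb1, Hif1a, Vegfa, Hmox1, Bcl2, Bdnf, Th and Fos. Some genes that met the rule are not reported here. Shares of mitochondrial, ribosomal protein and top 20 transcripts, depth and detected genes were compared by exact permutation tests. The relation between the 2 treatment steps was set against 20 simulations of unchanged groups and against every division of the MSC libraries into 2 pairs. The test was tried on simulated data with known fold changes, where 5.97% to 7.43% of calls were false. These simulations drew each gene independently, while the real libraries shared spread across genes. That rate is thus not an estimate for the real calls.

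Alternatives listed beforehand were median ratio scaling, upper quartile scaling, the Wald test of DESeq2 1.42.0, limma voom with quality weights, no filter, a filter of 1 CPM in 4 libraries, a fit of the 8 compared libraries, the replicate number as a block, a 2-fold limit, a threshold of 0.01, robust variance shrinkage, and leaving out each library. For lists they were an estimated correlation, the fry test, median ratio scaling, the block and leave-one-out. Alternatives added after results were seen were the removal of replicate 3 of MSC and of rTMS_MSC together, a residual component as a covariate, and scores on the main axis of spread within the OGDR libraries as a covariate, with the axis taken over all genes or over genes of log2 CPM of at least 3, 5 or 7. A list of glucocorticoid-responsive genes was also added then. Gene length, base composition and position were not used here.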

Results

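Bulk RNA sequencing of rat cells labelled PC12 was analysed in 12 libraries, 4 in each of 3 groups. All cells had gone through oxygen-glucose deprivation and reoxygenation (OGDR). The OGDR group had no further treatment, the MSC group was combined with mesenchymal stem cells, and the rTMS_MSC group had the stem cells and 10 Hz repetitive transcranial magnetic stimulation. The labels give 48 h after treatment as the time for every library. Counts in genes came to 18246250 to 20471838 per library, and 16707 to 16964 genes had at least 1 count. The edgeR quasi-likelihood (QL) test with Benjamini-Hochberg adjustment covered 13692 genes in a fit of all 12 libraries. A gene is said to rise, fall or change only where its adjusted p was under 0.05, and log2 fold changes are given with their standard errors where an error is printed. No group without deprivation was analysed here, so no value is a distance from undamaged cells. The labels do not say whether the 4 samples of a group were separate cultures, so all p-values measure only the spread between these samples.

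The 3 groups separated on the main principal component, which carried 33.68% of the variance. Scores on it ran from -33.1 to -26.6 in OGDR, from 2.54 to 12.4 in MSC and from 15.2 to 30.9 in rTMS_MSC. The next component carried 18.11% and was set mostly by rTMS_MSC 3 (32.4) and MSC 3 (-30.8). Transcripts of the mitochondrial genome made up 3.42 ± 0.210% of counts in OGDR, 2.76 ± 0.209% in MSC and 3.06 ± 0.188% in rTMS_MSC (mean ± SD, n = 4). Ribosomal protein transcripts made up 2.89 ± 0.108%, 2.49 ± 0.106% and 2.92 ± 0.318%, with rTMS_MSC 3 at 3.37%. The 20 most abundant genes held 8.93 ± 0.129%, 7.43 ± 0.170% and 7.89 ± 0.178% of counts. An exact permutation test of 4 libraries against 4 cannot fall below p = 0.0286. None of the 15 tests of library properties passed after adjustment (lowest adjusted p = 0.0612). Tests at that limit were the mitochondrial, ribosomal and top 20 shares in MSC against OGDR. The ribosomal and top 20 shares in rTMS_MSC against MSC, and the mitochondrial and top 20 shares in rTMS_MSC against OGDR, were there too. In each of these the groups did not overlap, so the adjusted values do not show that composition was alike. The biological coefficient of variation was 0.0937.

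**Figure D1:**
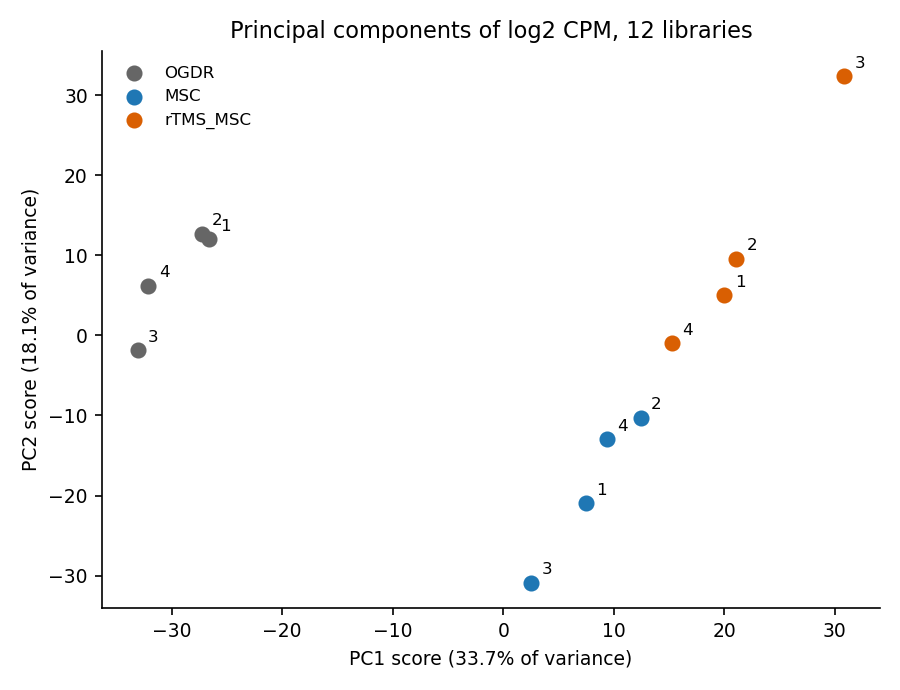
Scores of the 12 libraries on the 2 main principal components of log2 CPM (x, PC1; y, PC2), coloured by group and numbered by replicate. The groups separate along PC1, and replicate 3 of MSC and of rTMS_MSC lie at opposite ends of PC2.

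The cells carry a label that names an adrenal chromaffin tumour line, and such cells are known for making catecholamines and storing them with chromogranins. Levels of the marker lists were therefore read off in all 12 libraries, and the markers named here were picked after their levels were seen. Of 28 chromaffin genes, 14 stayed under 1 CPM in every library, 6 had no count at all, and 4 reached a mean of 10 CPM. Th, the rate-limiting enzyme of catecholamine synthesis, averaged 0.479 CPM, Dbh, which makes noradrenaline, 0.638 CPM, and the granule protein Chga 0.0722 CPM. Ddc, which makes dopamine, had 0 counts in all 12 libraries. Scg2, a granule protein, was an abundant member at 234 CPM. The glial and Schwann cell list was present at higher levels, with 8 of 12 genes at 10 CPM or more. Sox10, the lineage regulator of Schwann cells, averaged 397 CPM, S100b 257.5 CPM and Erbb3 142 CPM. In OGDR, which had no stem cells, Sox10 stood at 362 CPM and Erbb3 at 144 CPM. Among stromal genes the secreted protein Fstl1 (1038 CPM) and the collagen chain Col6a1 (994 CPM) were abundant, while Col1a1 (5.06 CPM in OGDR) and Col3a1 (0.764 CPM over all) were low and Lum had no count.

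**Figure D2:**
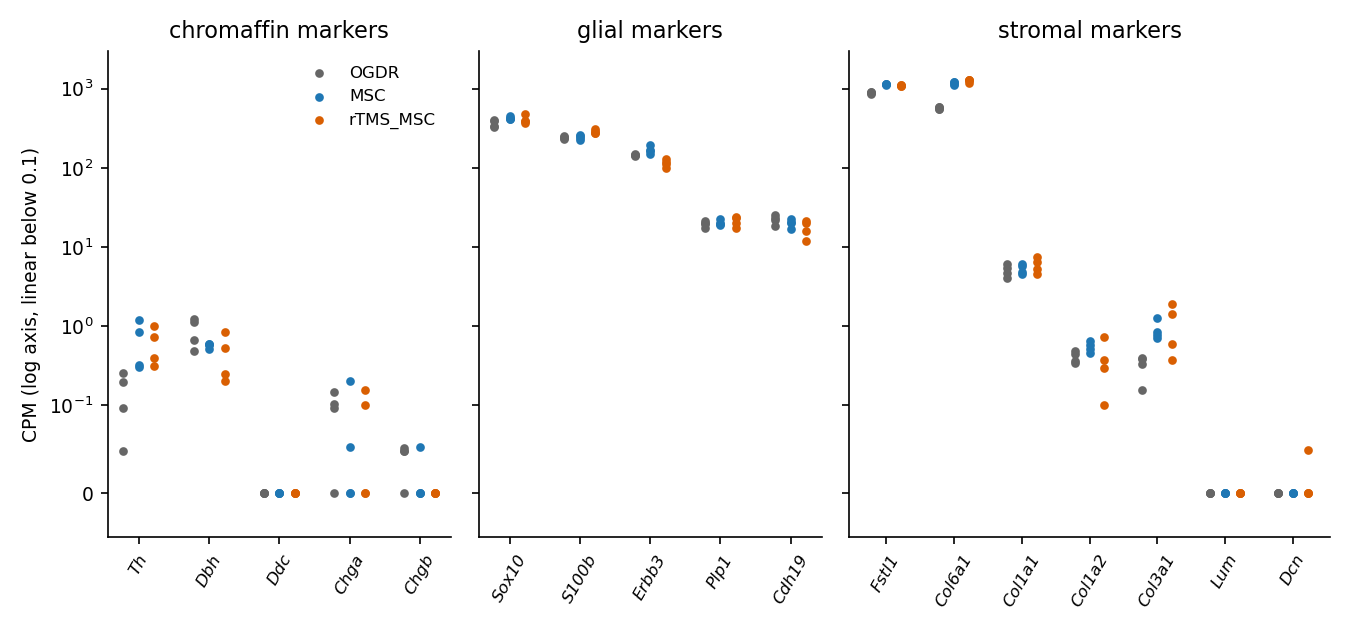
Levels of 17 marker genes in each of 12 libraries (y, CPM on a log axis that is linear under 0.1; x, gene), coloured by group. Chromaffin markers lie near 0 and glial markers above 10 CPM in all 3 groups.

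Mesenchymal stem cells release growth factors, cytokines and vesicles, and they have been studied as a treatment after ischaemic injury. Deprivation of oxygen and glucose followed by reoxygenation brings energy failure, oxidative damage and inflammatory signalling. The comparison of MSC with OGDR asked which transcripts differed once stem cells were added to deprived cells. The species of the stem cells and the way they were brought together with the labelled cells are not given in the sources used here, so a changed level is not assigned to either cell type. Of the 13692 genes, 2763 (20.2%) changed, 1582 up and 1181 down. At least a 2-fold difference was estimated for 309 of these (227 up, 82 down), and the median size among changed genes was 0.38 log2 units.

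Among genes that met the naming rule, the 3 largest rises were in genes under 1 CPM in OGDR. Orm1, an acute-phase plasma protein, had 0 counts in OGDR and 12.8 ± 2.93 CPM in MSC (mean ± SD, n = 4), a rise of at least 346.5-fold. Mlc1, an astrocyte membrane protein, had 1 count in OGDR and 6.58 ± 0.931 CPM in MSC, a ratio of 532.5 with an interval of 95.13 to 21070. Such floors and intervals cover counting error only. Sult1a1, which sulfates phenols and catecholamines, rose from 0.282 to 31.0 CPM (log2 fold change 6.74 ± 0.195, adjusted p = 9.47e-16). Tent5b, a poly(A) polymerase, rose by 3.77 ± 0.168, and the tetranectin gene Clec3b by 3.00 ± 0.248. Shroom3, which shapes epithelial cells through actin, rose by 2.95 ± 0.141. Tril, an accessory protein of Toll-like receptors, rose by 2.90, and Lrrc32, which holds latent TGF-beta at the cell surface, by 2.87 ± 0.252. The largest fall by that rule was in the glycoprotein hormone subunit Gpha2, which went from 18.1 to 0.728 CPM (-4.62 ± 0.242, QL test, adjusted p = 1.25e-11). The interferon-responsive factor Batf2 fell by 2.04 ± 0.158, the chemokine Ccl4 by 1.70 ± 0.154 and the actin-severing protein Scin by 1.64. The monocyte chemokine Ccl7 fell from 135 to 45.4 CPM (-1.57 ± 0.0666). S1pr1, Mcoln3 and Pde2a, a receptor, a lysosomal channel and a phosphodiesterase, changed by -1.56, -1.55 and -1.44.

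Inflammatory signals were lower in part. Of 21 tested cytokine and chemokine genes, 1 rose and 8 fell (2 and 8 when adjusted over the list alone), and the list was lower (camera adjusted p = 0.000497). It did not pass when the correlation between its genes was estimated (adjusted p = 0.196 with an estimated correlation). Every list test used a preset correlation of 0.01 unless an estimated one is named. Ccl2, which draws monocytes, fell from 832 ± 19.0 to 341 ± 12.8 CPM (mean ± SD, n = 4; log2 fold change -1.29 ± 0.0524, adjusted p = 2.34e-13), while the macrophage growth factor Csf1 rose by 0.61. The NF-kB list did not pass (33 tested, 7 up and 3 down, 8 and 3 over the list alone, adjusted p = 0.536), although its feedback inhibitors Nfkbiz and Nfkbia rose by 0.86 and 0.53. Among 15 inflammasome genes 2 rose and 2 fell (3 and 2 over the list alone, adjusted p = 0.961). Txnip, which binds thioredoxin and the NLRP3 sensor, rose by 2.47 ± 0.152, and Nlrp3 itself fell by 1.33 ± 0.279 (adjusted p = 0.00154). Interferon and antigen presentation genes were mixed, with 2 of 29 up and 3 down, also over the list alone (adjusted p = 0.615). The macrophage list (5 tested, 0 up and 1 down, adjusted p = 0.421) and the endothelial list (6 tested, 1 up and 1 down, adjusted p = 0.868) did not pass either. The endothelial median was -0.02 against a mean of 0.02.

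Lists tied to low oxygen and to energy supply differed in how many of their genes fell. The hypoxia list had 6 genes up and 16 down among 30 (8 and 16 over the list alone, adjusted p = 0.00156, adjusted p = 0.106 with an estimated correlation). Vegfa, the vascular growth factor, fell by 0.65 ± 0.0706 and the mitophagy receptor Bnip3 by 0.99, whereas the mTORC1 inhibitor Ddit4 rose by 1.27. Hif1a, the oxygen-sensing factor itself, fell by 0.49 (adjusted p = 0.00128). Glycolysis came just short of the threshold (18 tested, 3 up and 10 down, 4 and 10 over the list alone, adjusted p = 0.0526), with the kinases Pgk1 at -0.39 and Pfkm at 0.52. All 13 genes of the mitochondrial genome were tested, 12 fell (13 over the list alone), and the list was lower (adjusted p = 2.51e-09, adjusted p = 0.196 with an estimated correlation). Mt-atp6 and Mt-cyb, subunits of ATP synthase and of complex III, changed by -0.43 and -0.34. Nuclear-encoded respiratory chain genes gave a lower list (46 tested, 0 up and 2 down, 0 and 0 over the list alone, adjusted p = 0.0214, adjusted p = 0.633 with an estimated correlation), and did not pass without OGDR 2 (adjusted p = 0.127), MSC 1 or MSC 3.

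Of the lists for cell stress, those for the integrated stress response and the antioxidant response were lower. The integrated stress response had 1 gene up and 19 down among 27 (1 and 21 over the list alone), with a median log2 fold change of -0.47 (adjusted p = 1.20e-13, adjusted p = 0.106 with an estimated correlation). The glutathione-degrading enzyme Chac1 fell by 1.23 ± 0.0942, the pseudokinase Trib3 by 1.19 ± 0.0981, and the regulator Atf4 by 0.76 ± 0.0588. The antioxidant list was lower as well (27 tested, 2 up and 10 down, 2 and 11 over the list alone, adjusted p = 0.00156, adjusted p = 0.196 with an estimated correlation), with the haem-degrading enzyme Hmox1 going from 442 to 257 CPM (-0.78 ± 0.0601) and its activator Nfe2l2 at -0.385. Chaperones of the endoplasmic reticulum did not pass (20 tested, 2 up and 0 down, 0 and 0 over the list alone, adjusted p = 0.536). Heat shock genes did not pass (18 tested, 2 up and 5 down, 2 and 8 over the list alone, adjusted p = 0.292), and their median of -0.08 and mean of 0.07 differed in sign while the test pointed down. Cryab, the small heat shock protein that most raised that mean, went from 165 to 506 CPM (1.61 ± 0.0790).

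Lists for growth arrest and cell death showed no common direction. The p53 list had 2 genes up and 3 down among 21 (the same over the list alone, adjusted p = 0.615, median -0.01, mean 0.01), including the DNA damage gene Gadd45a at -0.77. Apoptosis had 3 up and 2 down among 23 (the same over the list alone, adjusted p = 0.961, median -0.03, mean 0.02). In it the survival protein Bcl2l1 rose by 0.62 and the killer protein Bmf by 0.79. Ferroptosis and iron handling had 5 up and 5 down among 17 (6 and 6 over the list alone, adjusted p = 0.178), with the transferrin receptor Tfrc at -0.85. Autophagy and lysosome genes had 3 up and 2 down among 30 (the same over the list alone, adjusted p = 0.578, median 0.00, mean -0.01), with the receptor Optn at -0.535.

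Growth and signalling lists were split. The DNA replication list was slightly higher (35 tested, 9 up and 0 down, 11 and 0 over the list alone, adjusted p = 0.00333, adjusted p = 0.231 with an estimated correlation), among them the helicase subunit Mcm2 at 0.28. The mitosis list came just short of the threshold (34 tested, 4 up and 0 down, 3 and 0 over the list alone, adjusted p = 0.0501), with the kinase Aurkb at 0.33. The ERK feedback list was lower (17 tested, 3 up and 9 down, 3 and 12 over the list alone, adjusted p = 0.000582, adjusted p = 0.118 with an estimated correlation). The receptor kinase inhibitors Spry4 and Spry1 went opposite ways, at -0.86 and 1.24. Immediate early genes did not pass (26 tested, 6 up and 11 down, 8 and 11 over the list alone, adjusted p = 0.536), and a median of -0.15 stood against a mean of 0.04. The clock gene Per1 in this list rose 6.18-fold (2.63 ± 0.0696, adjusted p = 2.29e-16), and Fos rose by 0.90 ± 0.115.

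Of the neuronal lists, only neurite outgrowth passed. The neurite outgrowth list had 9 of 20 genes up and 2 down, also over the list alone (adjusted p = 0.000104), and it alone still passed with an estimated correlation (adjusted p = 0.0344 with an estimated correlation). Crmp1, a mediator of semaphorin signals, rose by 0.99 ± 0.0544, the adhesion molecules L1cam and Ncam1 by 1.08 ± 0.120 and 0.8355, and the microtubule protein Map1b by 0.85. Over its tested members the log2 fold changes ran from -3.28 to 1.08, so the member furthest from 0 was lower. Neurotrophic genes did not pass (19 tested, 6 up and 3 down, 6 and 4 over the list alone, adjusted p = 0.178). The trophic factor Bdnf fell by 0.99 ± 0.265 (adjusted p = 0.00992). Synaptic vesicle genes (16 tested, 3 up and 1 down, 3 and 2 over the list alone, adjusted p = 0.536) and ion channels (18 tested, 4 up and 0 down, also over the list alone, adjusted p = 0.123) did not pass. The chromaffin list did not pass (14 tested, 4 up and 1 down, 5 and 1 over the list alone, adjusted p = 0.374), and within it Cyb561, which recycles ascorbate in secretory granules, rose by 1.84. Th rose by 2.13 ± 0.629 (adjusted p = 0.0195), but only from 0.151 to 0.673 CPM, and it did not pass without any of 4 single libraries.

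The matrix list and the stromal and glial marker lists were higher. Extracellular matrix genes had 12 up and 3 down among 28 (13 and 4 over the list alone, adjusted p = 0.000104, adjusted p = 0.0761 with an estimated correlation), with the collagen chains Col6a2 at 1.17 ± 0.0563 and Col4a1 at 0.79. The stromal marker list was higher as well (20 tested, 9 up and 2 down, 9 and 3 over the list alone, adjusted p = 0.00233, adjusted p = 0.196 with an estimated correlation), and among its members Col6a1 went from 564 to 1164 CPM. Targets of TGF-beta and YAP did not pass as a list (25 tested, 7 up and 6 down, 8 and 7 over the list alone, adjusted p = 0.0983). Within it the matrix protein Thbs1 rose by 1.84 and the matricellular growth regulator Ccn2 by 1.48. The glial marker list was higher (10 tested, 5 up and 0 down, 6 and 0 over the list alone, adjusted p = 0.00233, adjusted p = 0.0761 with an estimated correlation), with the filament protein Gfap at 1.19 and the lineage factor Olig2 at 0.68.

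The cholesterol biosynthesis list was lower by small amounts (23 tested, 0 up and 10 down, 1 and 11 over the list alone, adjusted p = 0.000721, adjusted p = 0.196 with an estimated correlation), such as the demethylase Cyp51 at -0.23. Fatty acid genes did not pass (17 tested, 5 up and 0 down, also over the list alone, adjusted p = 0.319), although their regulator Srebf1 rose by 1.39. Of 67 cytosolic ribosomal protein genes 33 fell and 0 rose (42 and 0 over the list alone), with a median of -0.23 (adjusted p = 8.01e-14, adjusted p = 0.379 with an estimated correlation). In all, 14 of the 34 lists passed, 5 up and 9 down, and 1 did with an estimated correlation. Of the panel genes, Il6 (adjusted p = 0.398), Tnf (adjusted p = 0.609), Nfkb1 (adjusted p = 0.138) and Bcl2 (adjusted p = 0.872) did not pass. Il1b had 7 counts and was not tested. In simulated counts with the same spread per gene the test recovered 32.84% of genes at the smallest change tried and 80.6% at 1.5-fold. A gene that did not pass is thus not shown to be unchanged. The genes changed in that trial averaged at least 1 CPM, so recovery of scarcer genes was not measured.

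**Figure D3:**
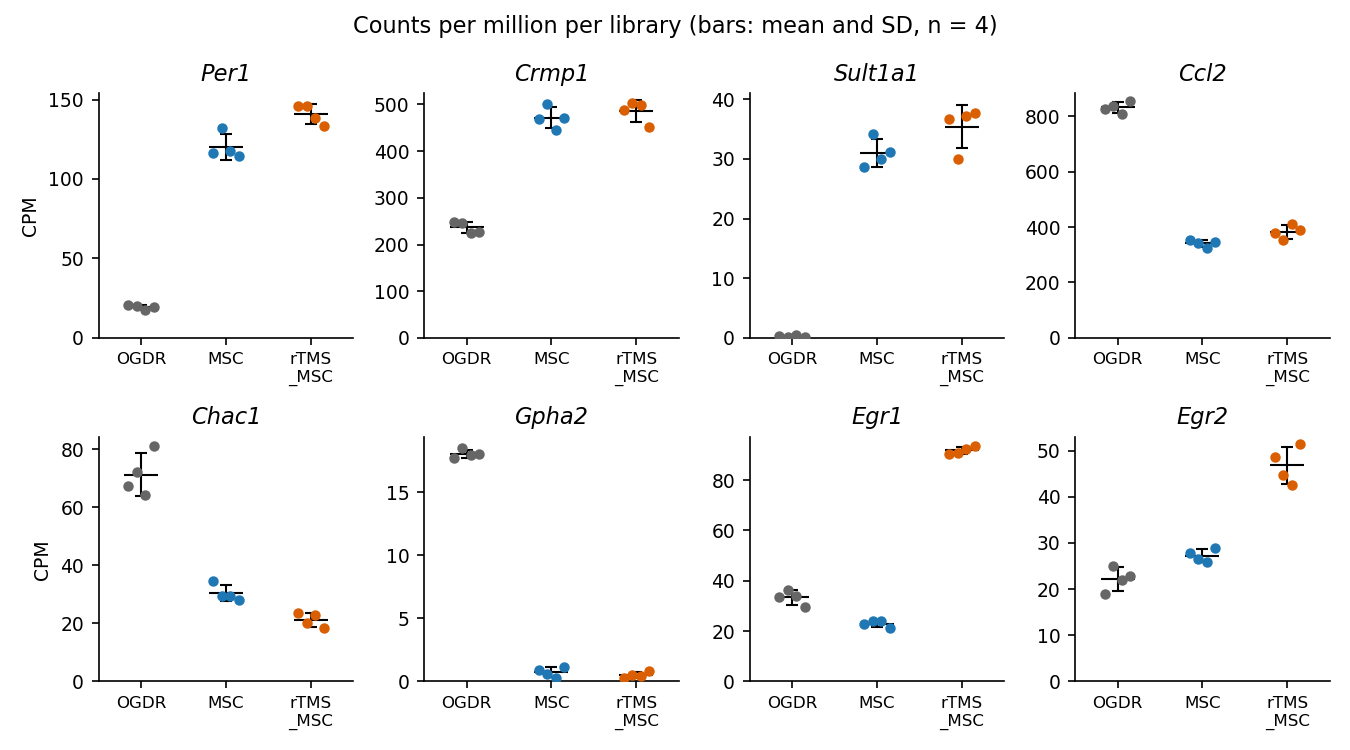
Levels of 8 genes in each library (y, CPM; x, group; bars, mean and SD of 4 libraries). Per1, Crmp1 and Sult1a1 are higher and Ccl2, Chac1 and Gpha2 lower in MSC and rTMS_MSC, while Egr1 and Egr2 are highest in rTMS_MSC.

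Repetitive magnetic stimulation induces electric currents in tissue, and in neurons it is known to switch on activity-dependent genes such as those of the Egr family. Immediate early genes of this kind respond within an hour and usually return to baseline soon after a stimulus. The libraries here are labelled 48 h after treatment, and no earlier time was among those analysed. The comparison of rTMS_MSC with MSC asked what the stimulation changed when stem cells were present in both groups. No group was stimulated without stem cells, so an effect of stimulation alone was not measured. Of the 13692 genes, 2475 (18.1%) changed, 977 up and 1498 down, with a median size of 0.33. Only 108 of them differed by at least 2-fold, 16 up and 92 down.

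Among genes that met the naming rule, the largest rise was in Egr1, a zinc finger factor that neuronal activity induces. It rose 3.99-fold from 23.0 ± 1.26 to 91.8 ± 1.45 CPM (mean ± SD, n = 4), a log2 fold change of 2.00 ± 0.0754 (QL test, adjusted p = 6.94e-13). Against OGDR the rise of Egr1 was smaller, as its level in MSC lay below that in OGDR. Its relative Egr2, which also drives myelination in Schwann cells, rose from 27.3 to 46.8 CPM (0.78 ± 0.0906, adjusted p = 0.000240). The flow-sensitive factor Klf2 rose by 0.94 ± 0.188 (adjusted p = 0.00327), the ubiquitin ligase Marchf10 by 0.84 ± 0.145, and Rgs16, which shortens G protein signals, by 0.66 ± 0.0819. Arid5a, which stabilises inflammatory messages, rose by 0.65 ± 0.0889. Hoxb5 and Acad11 rose by 0.71 and 0.67, but did not pass without replicate 3 of both groups. The immediate early list as a whole did not pass (26 tested, 6 up and 3 down, also over the list alone, adjusted p = 0.0542), although Junb rose by 0.37. Fos was at 0.15 and did not pass (adjusted p = 0.357).

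Falls of at least 2-fold outnumbered such rises, although among genes that met the naming rule the largest change was the rise of Egr1. Spopl, a ubiquitin ligase adaptor, fell by 1.78 ± 0.290, the RNA-binding protein Ro60 by 1.77 ± 0.258, and the activin subunit Inhba by 1.67 ± 0.268. The copper transporter Atp7a went from 21.5 to 7.47 CPM (-1.52 ± 0.224). Lmbrd2, Bend4, Fam199x and Ptpn4 fell by 1.51, 1.49, 1.47 and 1.43. Xiap, which blocks caspases, fell by 1.22 ± 0.215, and the calcium channel subunit Cacna2d1 by 1.16 ± 0.176. The ion channel list was lower (18 tested, 0 up and 5 down, also over the list alone, adjusted p = 0.0328, adjusted p = 0.418 with an estimated correlation), with the calcium release channel Itpr1 at -0.45 and the calcium pump Atp2b1 at -0.42. Without rTMS_MSC 4 that list did not pass (adjusted p = 0.0649). The extracellular matrix list was lower too (28 tested, 0 up and 7 down, 0 and 8 over the list alone, adjusted p = 0.0328, adjusted p = 0.418 with an estimated correlation), including the collagen receptor subunit Itga1 at -0.84, Col12a1 at -0.48 and fibronectin (Fn1) at -0.25. It did not pass without MSC 2 (adjusted p = 0.0809) or without rTMS_MSC 1 (adjusted p = 0.0699).

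The lists for protein synthesis and respiration were higher by small amounts. Of 67 ribosomal protein genes 52 rose and 0 fell (63 and 0 over the list alone, adjusted p = 1.86e-21, adjusted p = 0.418 with an estimated correlation), such as Rpl5 and Rps24 at 0.31 and 0.33. The mean score of this list was 0.3738 in rTMS_MSC 3 and -0.0401 to 0.0735 in the other 3 rTMS_MSC libraries, against -0.2394 to -0.0899 in MSC. Its median log2 fold change of 0.27 became 0.10 with each library's score on the main axis of spread within OGDR as a covariate (axis over genes of log2 CPM of at least 5), and 0.23 with the axis over all genes. Respiratory chain genes of the nucleus had 29 up and 1 down among 46 (35 and 1 over the list alone, adjusted p = 1.17e-11, adjusted p = 0.418 with an estimated correlation), with the complex I subunit Ndufv2 at 0.30. Here too rTMS_MSC 3 stood apart, with a list score of 0.3113 against 0.0238 to 0.095 in the other 3. Both lists still passed without replicate 3 of both groups. The mitochondrial genome had 5 of 13 up (9 up and 1 down over the list alone, camera adjusted p = 0.00143, adjusted p = 0.563 with an estimated correlation), with Mt-nd3 at 0.40 and Mt-co2 at 0.29. It did not pass without rTMS_MSC 4 (camera adjusted p = 0.0611). The list score was 0.1442 in rTMS_MSC 4, while the other rTMS_MSC libraries (-0.1464 to -0.0452) lay below MSC 4 (-0.0208). Glycolysis had 2 up and 1 down among 18 (6 and 1 over the list alone, adjusted p = 0.0328, adjusted p = 0.563 with an estimated correlation), and any of 4 libraries could be removed to lose that result.

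The interferon, antioxidant and cytokine lists were higher by small amounts, and their list scores overlapped between the groups. The interferon score of MSC 4 was 0.0597, within the rTMS_MSC range of 0.0528 to 0.1071. The antioxidant score of rTMS_MSC 1 was -0.0588, within the MSC range of -0.0981 to -0.0404. The cytokine score of rTMS_MSC 2 was -0.0987, within the MSC range of -0.3848 to -0.0931. Interferon and antigen presentation genes had 9 up and 2 down among 29 (12 and 2 over the list alone, adjusted p = 0.000979, adjusted p = 0.418 with an estimated correlation), with the light chain of class I molecules B2m at 0.28 and the antiviral tether Bst2 at 0.41. Antioxidant genes had 10 up and 3 down among 27 (12 and 3 over the list alone, adjusted p = 0.00699, adjusted p = 0.418 with an estimated correlation), among them the peroxidase Prdx1 at 0.29 and the iron store Fth1 at 0.32, while the glutathione conjugate pump Abcc1 fell by 0.70. Cytokines had 5 up and 1 down among 21 (7 and 1 over the list alone, adjusted p = 0.0328, adjusted p = 0.563 with an estimated correlation), and they did not pass without replicate 3 of both groups (adjusted p = 0.0890). In all 9 of the 34 lists passed, 7 up and 2 down, and none did with an estimated correlation (lowest adjusted p = 0.418). Of lists that did not pass, neurite outgrowth had 3 genes up and 7 down (adjusted p = 0.774) and pointed down against a median of 0.04 and a mean of 0.03. In it Dpysl3 fell by 0.74 and Map1b by 0.51, and the microtubule regulator Stmn1 rose by 0.29. The integrated stress response had 3 up and 2 down (adjusted p = 0.206), with Chac1 at -0.52, and the ERK feedback list 1 up and 4 down (adjusted p = 0.343), with the phosphatase Dusp6 at -0.39. Inflammasome genes (adjusted p = 0.71) had a median of 0.15 and a mean of -0.02.

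Many of these calls were lost without certain libraries. The number of changed genes fell to 1006 without MSC 3, to 1313 without MSC 1, and to 677 without replicate 3 of both groups, of which 666 were among the 2475. It was 1480 without rTMS_MSC 3, 2451 without MSC 2 and 3196 without rTMS_MSC 4. Without replicate 3 of both groups the 2475 genes kept a median of 70.95% of their log2 fold change. Egr1, Egr2, Klf2, Arid5a, Xiap, Atp7a and the other falls named by size kept their calls under each change of scaling, filter, test and libraries. Fits with an OGDR axis score as a covariate are not among these changes. With them 2208 of the 2475 calls remained when the axis used all genes. When it used genes of log2 CPM of at least 3, 5 or 7, there remained 779, 821 or 876.

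The comparison of rTMS_MSC with OGDR asked how far cells given stem cells and stimulation differed from deprived cells without either. It adds together the changes of the other 2 comparisons, so it is not a separate line of evidence on them. Of the 13692 genes, 4439 (32.4%) changed, 2215 up and 2224 down, with a median size of 0.40. At least 2-fold differences were estimated for 275 genes up and 135 down.

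The largest changes by the naming rule were mostly those already present with stem cells alone. Orm1 rose at least 365.2-fold, Mlc1 had a ratio of 557.2 with an interval of 99.57 to 22050, and Sult1a1 rose by 6.93. Per1 went from 19.4 to 141 CPM (2.86 ± 0.0698), and the cell adhesion protein Cadm3 rose by 3.01. Gpha2 fell by 5.12, the calcium-regulating hormone Stc1 by 1.75, and the laminin chain Lama3 by 1.58. Spopl and Ro60 fell by 1.70 and 1.56, which were changes that came with the stimulated group. Ccl2 and Ccl7 fell by 1.12 and 1.55, yet the cytokine list did not pass (3 up and 5 down, adjusted p = 0.151). Nfkbia and Nfkbiz rose by 0.93 and 1.15, Egr1 by 1.46, Klf2 by 2.25, Fos by 1.05, and Txnip by 2.84. Hif1a fell by 0.83 and Vegfa by 0.90, while Bcl2, Il6 and Tnf did not pass.

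Of the 34 lists 9 passed, 4 up and 5 down, and none with an estimated correlation. The DNA replication list (18 up and 1 down, 19 and 1 over the list alone, adjusted p = 0.00299, adjusted p = 0.314 with an estimated correlation) and the nuclear respiratory chain list (12 up and 0 down, adjusted p = 0.00299, adjusted p = 0.782 with an estimated correlation) were higher, with the flap endonuclease Fen1 at 0.38 and Ndufv2 at 0.27. The respiratory list score was 0.3113 in rTMS_MSC 3 against 0.0238 to 0.095 in the other 3 and up to 0.0509 in OGDR, and the list still passed without rTMS_MSC 3. The neurite outgrowth list was higher (10 up and 2 down, 10 and 3 over the list alone, adjusted p = 0.00371, adjusted p = 0.143 with an estimated correlation), with the neuronal tubulins Tubb2b and Tubb3 at 1.30 and 0.77. The glial marker list was higher (5 up and 1 down, 6 and 2 over the list alone, adjusted p = 0.0133, adjusted p = 0.157 with an estimated correlation), with Gfap at 1.24 and the lineage factor Olig1 at 0.91. The integrated stress response list was lower (1 up and 16 down, adjusted p = 2.86e-07, adjusted p = 0.314 with an estimated correlation), with Chac1 at -1.75 and the stress sensor Sesn2 at -0.75. Its score was 0.0412 in rTMS_MSC 3, nearer to OGDR (0.2473 to 0.332) than the other rTMS_MSC libraries (-0.2428 to -0.1444). The ERK feedback list was lower (2 up and 13 down, 2 and 14 over the list alone, adjusted p = 6.59e-05, adjusted p = 0.143 with an estimated correlation), with Spry4 at -1.15.

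The cholesterol list was lower (0 up and 12 down, 2 and 15 over the list alone, adjusted p = 0.00371, adjusted p = 0.383 with an estimated correlation), with the synthase Hmgcs1 at -0.47. The list of the mitochondrial genome was lower (0 up and 7 down, adjusted p = 0.00716, adjusted p = 0.756 with an estimated correlation), with Mt-nd5 at -0.57. Its score was 0.3249 in OGDR 4 and 0.114 to 0.1714 in the other OGDR libraries, and 0.1442 in rTMS_MSC 4, within the OGDR range, against -0.1464 to -0.0452 in the other rTMS_MSC libraries. The hypoxia list was lower (6 up and 15 down, 6 and 16 over the list alone, adjusted p = 0.00978, adjusted p = 0.205 with an estimated correlation), with Bnip3 at -0.90. The ribosomal list did not pass here (1 up and 0 down, adjusted p = 0.711). Matrix genes (adjusted p = 0.151), stromal markers (adjusted p = 0.187) and interferon genes (adjusted p = 0.0619) did not pass.

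**Figure D4:**
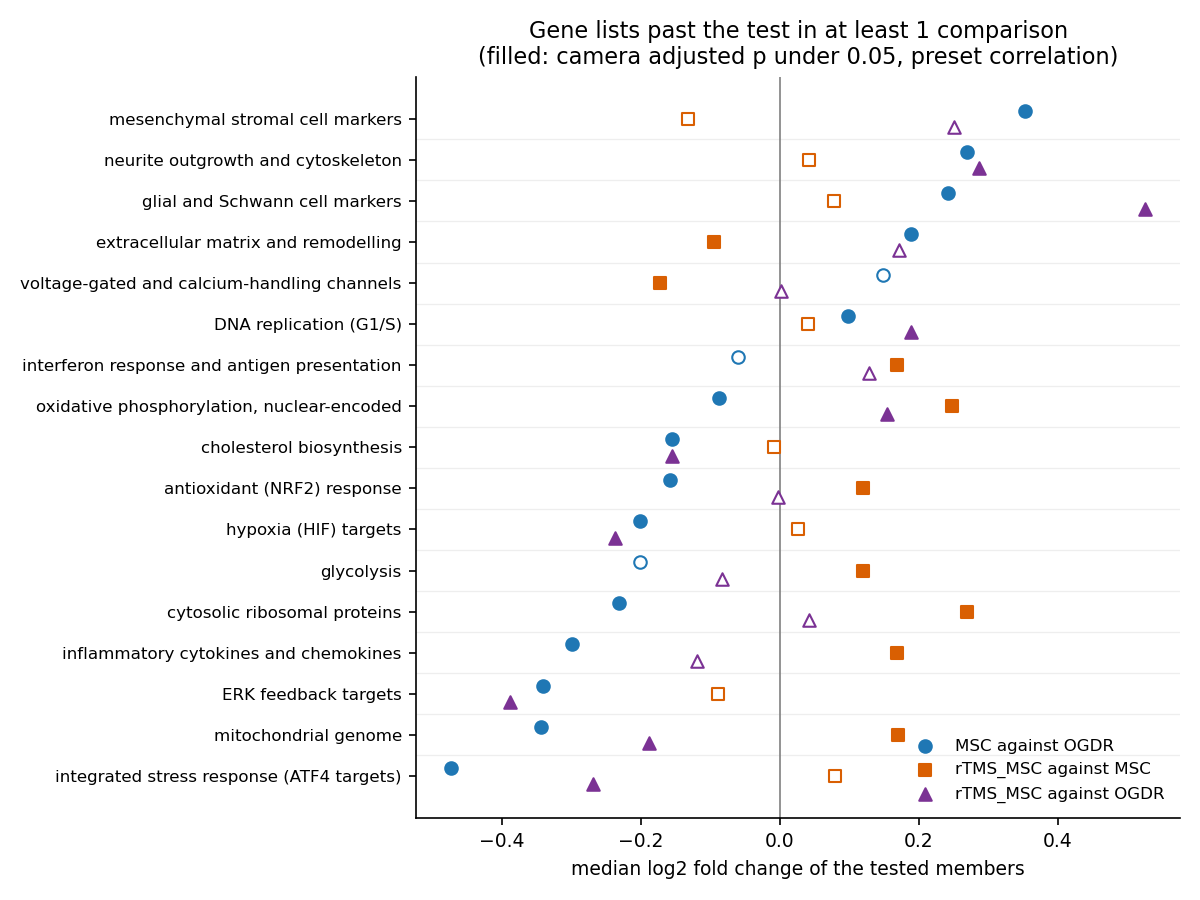
Median log2 fold change (x) of the tested members of each gene list (y) in the 3 comparisons, for lists past the camera test in at least 1 of them. Ribosomal, respiratory and mitochondrial medians lie under 0 with stem cells and above 0 with added stimulation, but the MSC libraries enter these 2 comparisons with opposite sign, which by itself favours opposite medians.

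A treatment given on top of another can push the same genes further or push them back. The question here was whether the genes that changed with stem cells moved back under stimulation. The correlation between the 2 sets of log2 fold changes was -0.2068 over 13692 genes, but the MSC libraries enter both sets with opposite sign, which by itself makes the correlation negative. In 20 simulations without any true difference it was -0.5006 on average (-0.5235 to -0.4697), so r alone does not separate the 2 cases. The covariance was -0.02829 against -0.01845 in the simulations (-0.01965 to -0.01631). With the MSC libraries divided so that each pair of them served only 1 comparison, the mean r was -0.05222, with a range from -0.1287 to 0.03093. By shared calls, 297 genes rose with stem cells and fell with stimulation, against 173.1 expected if the calls were independent, and 214 fell and then rose, against 84.27. Genes moving the same way in both steps numbered 71 up (112.9 expected) and 63 down (129.2 expected), but the shared MSC libraries lower these 2 overlaps and raise the other 2. Rpl5 had opposite signs, at -0.33 with stem cells and 0.31 with stimulation, and so had Map1b, at 0.85 and -0.51. Chac1 kept its direction, at -1.23 and -0.52. With divided MSC libraries the opposite-sign overlaps were 88.83 against 57.25 and 29 against 16.66 expected, while 32.67 genes rose in both steps against 28.31 expected and 26.5 fell in both against 34.1. The covariance lay below the simulated range, but the simulations drew each gene independently, while the real libraries shared spread across genes. That range is thus too narrow to judge the covariance by. With divided libraries the opposite-sign overlaps stayed above expectation, but shared rises did so too and r ranged across 0. Whether the stimulation moved genes back in general is left open.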

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

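The genes checked here are those named in the text and figures, most of them chosen only after the results had been seen, and no explanation was tested in this part. In 446 groups of 4 values (144 genes and the library properties), 27 held a library far from the other 3 by Dixon's test at 95%. Chance flags about 1 in 20 groups, which would be 22.3 here. Single libraries stood apart in library properties in OGDR replicate 4, with 19072047 counts in genes (others 20379393 to 20471838) and 3.72931% mitochondrial counts (others 3.29343 to 3.33422). The same library had Mt-co2 at 3668.6 CPM (others 3281.3 to 3341.8). In rTMS_MSC replicate 3 the genes Bcl2l1 (294.52 CPM, others 279.57 to 279.92), Itpr1 (64.67, others 82.018 to 85.4), Cadm3 (18.288, others 16.165 to 16.284), Cebpd (69.441, others 57.185 to 58.471) and Arl4d (25.815, others 17.678 to 19.006) stood apart. In MSC replicate 3 they were Fam199x (8.8789, others 3.7193 to 4.1054) and Bst2 (62.206, others 75.82 to 77.197).

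The remaining libraries that stood apart were spread over the groups. In OGDR they were Spopl in replicate 3 (11.041 CPM, others 6.26 to 6.6748) and, in replicate 2, Scin (8.9711, others 7.6005 to 7.7923) and Marchf10 (5.3235, others 5.1109 to 5.1429). In MSC they were Ddit4 (129.97, others 140.22 to 141.53) and Bmf (12.589, others 15.051 to 15.515) in replicate 1 and Cryab in replicate 2 (547.71, others 487.58 to 496.9). In rTMS_MSC they were Col6a1 (1177.4, others 1277.3 to 1286) and Hoxb5 (5.6666, others 5.0794 to 5.1418) in replicate 4, Sult1a1 in replicate 2 (30.014, others 36.751 to 37.71) and Ccn2 in replicate 1 (1913.2, others 1775.5 to 1789.9). Genes with almost no counts stood apart through a few reads, as the other 3 libraries had none. These were Mlc1 in OGDR replicate 4 (0.051949 CPM), Il1b in OGDR replicate 1 (0.097442), MSC replicate 1 (0.20143) and rTMS_MSC replicate 4 (0.050147), Dcn in rTMS_MSC replicate 1 (0.049798) and Chgb in MSC replicate 4 (0.053133). Chgb in OGDR replicate 2 was at 0 CPM, with the others at 0.048216 to 0.051949.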

How the results depend on the processing

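The joint removal of replicate 3 of MSC and rTMS_MSC and all covariates were chosen only after the results had been seen. Median ratio scaling, upper quartile scaling, DESeq2, voom with quality weights, both filters and robust shrinkage kept all 3 counts of changed genes within 1.5-fold and turned no called gene around, but with upper quartile scaling the share of rises was 50.40% (1446 up, 1423 down) in place of 57.26% for MSC against OGDR and 46.63% in place of 39.47% for rTMS_MSC against MSC. With the 8 compared libraries alone, rTMS_MSC against MSC had 568 genes up. Of 12900 checks on named genes 12186 kept their side of the threshold, 583 lost it, 126 gained it and 5 reversed, where a sign change of a gene that never passed counts as kept. With at least 2-fold differences the counts were 309 (227 up, 82 down) for MSC against OGDR, 108 (16, 92) for rTMS_MSC against MSC and 410 (275, 135) for rTMS_MSC against OGDR, and at a threshold of 0.01 they were 1743 (654 down), 858 (202, 656) and 2724 (1409, 1315), since fewer genes meet a stricter limit. Leaving out each library gave 2243 to 3451 genes (up 1341 to 1885, down 899 to 1566), 1006 to 3196 (up 282 to 1350, down 724 to 1846) and 3461 to 4683 (up 1759 to 2294, down 1702 to 2389), and 13 to 16, 5 to 9 and 9 to 15 lists, with r from -0.296 to -0.1933. Without both replicates 3, rTMS_MSC against MSC had 677 genes (154, 523) and rTMS_MSC against OGDR 15 lists. With an estimated correlation 1, 0 and 0 lists passed, and with fry 24, 14 and 18. The relation was -0.1579 over genes called in either comparison and -0.05222 with divided MSC libraries. With the OGDR axis over genes of log2 CPM of at least 3, 5 and 7, rTMS_MSC against MSC had 870 (259, 611), 933 (292, 641) and 996 (316, 680) genes, rTMS_MSC against OGDR 2519 (1359, 1160), 2441 (1320, 1121) and 2332 (1269, 1063), and MSC against OGDR 1866, 1894 and 1913 down. There 20, 75 and 172 of the 4439 genes called in rTMS_MSC against OGDR took the opposite sign, and of the named genes Rps16 reversed to -0.0055, -0.0333 and -0.0632, and Orai1 to -0.0031 and -0.0469 (at least 5 and 7). With the residual component, which is uncorrelated with the groups by construction and so hardly moves the fold changes, MSC against OGDR had 4306 (2025 down) and rTMS_MSC against MSC 4615 (2153, 2462). Where no reason is given, the cause was not tested. With the replicate block the counts were 2577, 1995 and 4185, and 15, 9 and 9 lists passed. Correlations of libraries with the same number were -0.2051 to 0.1276 (1 of 12 over 0.1), and 4 of 12 libraries correlated best with their own number, so the replicate block was not used elsewhere. At this depth a gene under 1 CPM has fewer than about 20 counts per library, and 7084 genes with counts fell short of the filter and were not tested.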

Other observations

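All explanations weighed here were chosen only after the comparisons had been seen, and only for the divisions of libraries and for the glucocorticoid list was the deciding value set down before the test was run.

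Glucocorticoid hormones act on cells through a receptor that switches on a well-known set of genes, among them its own brake Fkbp5. A list of such genes was put together after Per1, Orm1, Gpd1 and Sult1a1 had been seen to rise, and it leaves these 4 out. Of 21 tested members 11 rose and 2 fell in MSC against OGDR (12 and 3 over the list alone). Their median log2 fold change was 0.82 (camera unadjusted p = 2.04e-08, unadjusted p = 0.000784 with an estimated correlation). This list was tested alone, so its camera p-values were not adjusted over lists. They are not directly comparable with the adjusted p-values of the lists chosen beforehand. Fkbp5 rose from 84.2 to 335 CPM (1.99 ± 0.0607), the kinase Sgk1 from 61.7 to 233 CPM (1.92 ± 0.0653), and Tsc22d3, an anti-inflammatory mediator of the hormone, from 28.9 to 113 CPM (1.97 ± 0.0684). Fam107a rose by 2.12, the lipase inhibitor Angptl4 by 1.855, the iron carrier Lcn2 by 1.32, Cebpd by 1.22 and the glutamine synthetase Glul by 0.82. Slc38a2 and Arl4d fell by 0.38 and 0.36. In rTMS_MSC against OGDR 13 rose and 1 fell (camera unadjusted p = 2.50e-07, unadjusted p = 0.00133 with an estimated correlation). In rTMS_MSC against MSC the list did not pass (2 up and 2 down, camera unadjusted p = 0.777).

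The rise of Per1, Orm1, Gpd1 and Sult1a1 may come from glucocorticoid receptor activity, since 52.38% of the tested members of the separate list rose with them. What brought it about, such as hormone in a medium, was not tested. Transcripts of rat stem cells as a source were weighed by Col1a1, Col1a2, Col3a1, Lum and Dcn, whose summed rise of 0.9951 CPM was 0.1719% of the 579 CPM by which the 4 genes rose. These 5 genes were picked after values had been seen, and they speak against carry-over only if such cells express them. The stromal marker list as a whole was higher in the same comparison (9 up and 2 down, camera adjusted p = 0.00233, adjusted p = 0.196 with an estimated correlation). Its member Col6a1 rose by far more CPM than these 5 genes together, so the outcome depends on which stromal genes are chosen. Stem cells of another species were not tested.

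Chance placement of libraries was tested by dividing the 8 libraries of each comparison into groups of 4 in all 35 ways. In each of the 3 comparisons only 1 of the 35 divisions, the real one, called as many genes (2763, 2475 and 4439), and the highest other division called 0 with the edgeR test. At unadjusted p under 0.05 the highest other division had 1603, 3729 and 3048 genes, against 4381, 4645 and 5764 for the real one. The other divisions mix libraries of both groups, so any difference between the groups widens the spread and lowers their calls. The 0 calls thus add little to the rank of the real division. With 35 divisions chance cannot be excluded below 1 in 35, and the divisions do not separate treatment from any other difference between the groups.

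The changes between rTMS_MSC and MSC could stem from a few libraries or from a spread that treatment did not cause, and the limits of 25% and 50% used to judge this were set after values had been seen. Without replicate 3 of both groups the called genes kept a median of 70.95% of their log2 fold change, though only 666 of 2475 were still called. With each library's score on the main axis of spread within OGDR as a covariate they kept 93.7% when the axis used all genes, and 66.99% (38.94% to 98.9% for the middle 80% of genes, 821 still called) when it used genes of log2 CPM of at least 5. The ribosomal list kept 86.97% and 36.39% of its median, and Egr1, Egr2, Rgs16 and Arid5a kept 97.43% and 92.5%. By these limits neither explanation accounts for the changes as a whole. Most calls were lost without replicate 3 of both groups and with the second axis. The 1654 calls lost with the second axis went from a median size of 0.3096 to 0.1824. Their median standard error fell as well, from 0.08925 to 0.08129. Across genes the change correlated with that axis at 0.4786, and at 0.2995 without replicate 3 of both groups. With the axis over all genes these correlations were 0.1421 and 0.05986. A large partial cause thus stays open. For the Egr1 group the share kept was worked out only with the axis, which did not account for that rise. Egr1, Egr2 and Arid5a also kept their calls without replicate 3 of both groups. For the ribosomal rise, the second axis leaves open that a shared spread of the libraries caused much of it.

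The near absence of Chga and Ddc beside abundant Sox10 and S100b was weighed in 3 ways. For each of the 8 glial genes of at least 10 CPM, the level in OGDR, which had no stem cells, was divided by that in MSC. The median of these shares was 85.73%, so rat stem cells do not explain the level of a typical gene among the 8. In the glial list 5 of 10 tested genes rose in MSC, so a part of the level of single genes is not covered by this median. Cells of another type than the label names could explain the median chromaffin level of 0.3841 CPM against a glial median of 13.01 CPM, but this cannot be told from these data, as the limit was set after the values were seen. Loss of chromaffin transcripts after oxygen-glucose deprivation could explain the low chromaffin levels, but not by itself the abundant Sox10 and S100b. It could not be tested, as 0 libraries without deprivation were analysed.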
